A study of Mus musculus with 12 samples.

How the data were processed

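FoxP3 was immunoprecipitated with a rabbit polyclonal antibody from magnetically sorted CD4+ Treg cells of C57BL/6J mice, per the labels. About 10000000 cells per reaction were fixed for 30 min in 1% formaldehyde and 4 µg of antibody was used. The labels give 3 ChIP and 3 input libraries for each of the WT and A384T genotypes. Groups and replicate numbers came from the sample titles. Of these, the 6 ChIP libraries each have a peak list, and the inputs were not analysed here as samples of their own.

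The submitters' processing notes name Bowtie2, MACS2 and the genome build mm9. Peaks were called on each library separately with MACS 2.1.0.20140616 against 1 control library, which is named only by a code, at a q-value cutoff of 1e-10, per the file headers. Per the file headers 1 tag was kept per position and strand, and the larger of the ChIP and control sets was scaled towards the smaller. The deposited lists give for each peak its position, length and summit, the pileup (a signal value) at the summit, the -log10 p-value, the fold enrichment (a ratio of ChIP to local control background) and the -log10 q-value. The cutoff and the control limit which regions appear in a list: a region missing from a list had no peak past the cutoff, which does not show that nothing was bound there. Tags were 51 bp long in replicate 1 of both genotypes and 49 bp in the others, per the file headers, and redundant ChIP tags made up 39, 18 and 20% in WT replicates 1, 2 and 3 and 30, 19 and 21% in A384T replicates 1, 2 and 3.

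From the deposited lists, peaks on chromosomes 1 to 19, X and Y were kept. Peaks of different libraries that overlapped by at least 1 bp were joined into regions, and a region was present in a library that had a peak in it. Peak lists carry no scale shared between libraries, so libraries were compared by presence, by overlap of lists of equal length (the 1746 strongest by -log10 q) and by order within the regions present in all 6 libraries. Shares of regions have exact Clopper-Pearson intervals at 95%, and counts on unplaced sequences were set against the 3 counts that a count of 0 allows. Genotypes were compared with exact permutation tests over the assignments of 6 libraries to groups of 3, two-sided for values per library and one-sided for the overlap within minus between genotypes. Clustering of regions was tested with 10000 random draws. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.

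Named regions followed a rule: the 10 best-ranked regions present in all 6 libraries, in all 3 libraries of one genotype and none of the other, or in at least 2 where fewer than 10 met this, by the mean percentile of -log10 q within each list; the text gives the first of them. The first regions of each direction in the rank comparison and the row on chromosome 5 were chosen after their values were seen. The grouping, the tests, this rule and the first set of alternatives were fixed before the data were examined. The counts for 3 of 3 against none as results of their own, the rank comparison, the clustering windows and some alternatives were added after the data were seen.

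Alternatives were a fold of at least 5, -log10 q of at least 10 or 20, overlap of 50% of the shorter peak, summits within 200 bp, full lists, lists of 500 or 1746 peaks, lists matched in length between genotypes, all sequences, no chromosome Y, 1 Mb windows counted once, ranks by fold, replicate numbers as blocks, and each library left out in turn. The region joining and the rank comparison were run on simulated lists of 24765 regions. In these, 246 A384T regions and 53 WT regions were made restricted in 3 of 3, and all 246 and 53 were found. The simulated regions lay far apart and their peaks always overlapped, so full recovery checks the counting only. It does not show how joining behaves where peaks are wide or lie close together. Of 100 regions given shifts that were large against the simulated noise 99 were recovered, which says little about smaller shifts. In the same lists 15.5% of 853 unshifted regions were also called. With no shifts 9.02% of 953 regions were called.

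The gene table used here is of another mouse assembly than the peaks, so no coordinates were joined to it. The planned shares of peaks with a forkhead motif or near a promoter, and the planned counts for lists of Treg, effector, cofactor and other marker genes, were not analysed here. Regions are given by coordinates alone.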

Results

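FoxP3, the forkhead transcription factor of regulatory T (Treg) cells, was mapped by ChIP-seq in Treg cells from mice carrying either wild-type FoxP3 (WT) or FoxP3 with the substitution A384T (A384T). In both lines the FoxP3 gene carries a human CD2 reporter, which was used to isolate the cells magnetically from lymph nodes and spleen. The comparison asks where the substituted protein binds relative to the wild-type protein. There were 3 ChIP libraries per genotype, each with its own peak list in mm9 coordinates, and the labels name 6 input libraries that enter no comparison here. Peaks were called per library, so regions were compared as present or absent, and all positions below are mm9. After removal of duplicate tags the ChIP libraries held 17520951, 25386770 and 21752899 tags for WT replicates 1, 2 and 3, and 18255500, 22402648 and 24493840 tags for A384T replicates 1, 2 and 3. The labels do not say whether the replicates came from separate animals, so a p-value measures only the spread between these libraries, which may be technical.

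Both genotypes gave FoxP3 peaks in every library, and the number varied more between replicates than between genotypes. On the standard chromosomes WT replicates 1, 2 and 3 had 20723, 1746 and 3905 peaks, and A384T replicates 1, 2 and 3 had 18147, 6657 and 2050. The means were 8791 ± 10389 (SD, n = 3) for WT and 8951 ± 8290 (SD, n = 3) for A384T. On the log2 scale A384T lay 0.27 above WT, within the spread between replicates (two-sided exact permutation test, p = 0.8; the smallest p that 3 against 3 allows is 0.1). The difference turned to -0.52 without WT replicate 2 and to -0.50 without A384T replicate 1. The replicate 1 libraries were sequenced with 51 bp tags and the others with 49 bp tags. Within the 49 bp libraries the means were 2826 ± 1527 (SD, n = 2) for WT and 4354 ± 3258 (SD, n = 2) for A384T, and the 51 bp libraries gave 1 value per genotype. The longest lists came from the libraries with the fewest unique tags, and more unique tags went with fewer peaks except that A384T replicate 2 had more of both than WT replicate 3.

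**Figure D1:**
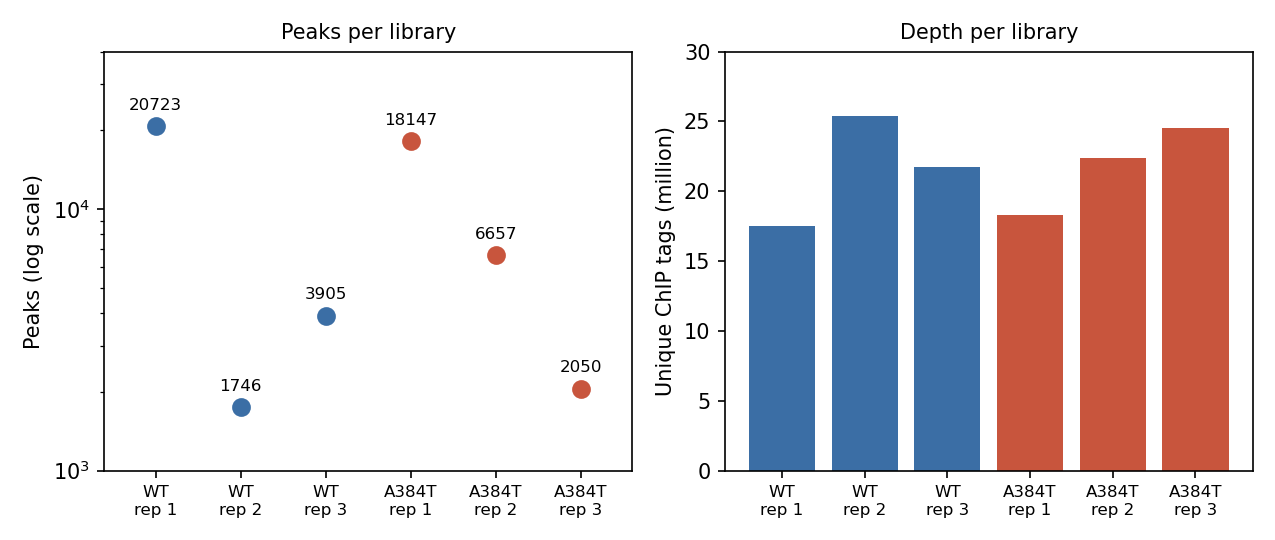
Peaks per library on a log axis (left) and unique ChIP tags per library (right), with WT in blue and A384T in red; each point or bar is 1 library. The replicate 1 libraries, with 20723 and 18147 peaks, lie above all others although they have the fewest unique tags.

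Most regions found repeatedly in one genotype were also found in the other. The 6 lists merged into 24765 regions, of which 13870 (56.0%) had a peak in both genotypes and 962 (3.89%) had one in all 6 libraries. Of the 1539 regions present in all 3 WT libraries, 1536 (99.8%) had a peak in at least 1 A384T library. Of the 1889 regions present in all 3 A384T libraries, 1843 (97.6%) had a peak in at least 1 WT library. Only the 962 had a peak in all 3 libraries of the other genotype. Just 1 WT library had a peak in 425 of the 1889, and just 1 A384T library in 37 of the 1539. A single library accounted for 10490 regions (42.4%), and 17618 regions (71.1%) were seen only in one or both replicate 1 libraries. Most regions of the shorter lists were contained in the long ones. WT replicate 1 held 97.3% of the regions of A384T replicate 3 (exact 95% interval 96.5 to 98.0%), and A384T replicate 1 held 98.7% of those of WT replicate 2 (98.1 to 99.2%) but 89.8% of those of WT replicate 3 (88.8 to 90.8%). These intervals, like all others given here, cover counting error only.

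**Figure D2:**
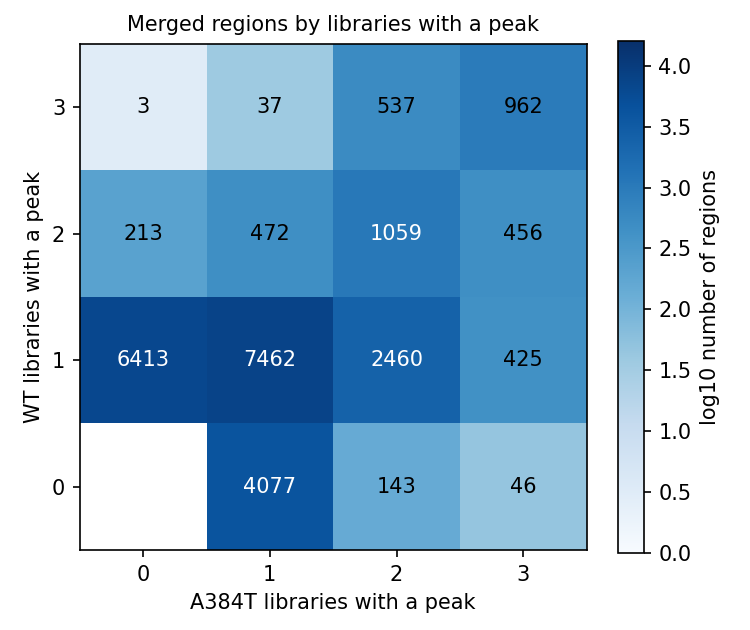
Number of merged regions by how many WT libraries (vertical axis) and A384T libraries (horizontal axis) had a peak there; shading gives the log10 number and the cell without a number is empty by construction. The largest single group is the 7462 regions with a peak in 1 library of each genotype, and 962 regions had a peak in all 6.

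The best-ranked regions of the shared set were strong in every library. First was chromosome 1 from 175328736 to 175329287, where the authors' fold enrichment over control averaged 72.3 ± 32.4 in WT and 60.95 ± 11.97 in A384T (SD, n = 3 each). It was followed by chromosome 10 from 28313434 to 28314231 (WT 49.9 ± 9.46, A384T 61.6 ± 23.2), chromosome 17 from 27340940 to 27341725 (WT 37.1 ± 15.1, A384T 48.6 ± 16.1) and chromosome 7 from 128850789 to 128851200 (WT 43.1 ± 2.99, A384T 40.6 ± 10.4). The other 6 of the 10 best-ranked lay on chromosomes 3, 11, 9, 2 and 14, with chromosome 9 holding a pair. Fold enrichment and q-value are the authors' own values per peak; they describe a peak within its list and were not used as a level to compare genotypes. Within their own lists the 962 shared regions had median rank percentiles of 96.9, 67.6 and 84.8 in WT replicates 1, 2 and 3 and of 93.8, 90.5 and 63.3 in A384T replicates 1, 2 and 3.

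The strongest peaks were shared more within a genotype than between genotypes. With every list reduced to its 1746 strongest peaks, the length of the shortest list, the Jaccard index (shared over combined regions, overlap of at least 1 bp) averaged 50.5% among WT libraries (range 49.5 to 51.1%) and 45.8% among A384T libraries (42.9 to 51.2%). Between genotypes it averaged 37.4% over 9 pairs, from 26.4% for WT replicate 2 with A384T replicate 1 to 46.6% for WT replicate 1 with A384T replicate 2. The highest value between genotypes exceeded 2 of the 3 values among A384T libraries. The index within genotypes was higher by 0.108 than between them, the largest difference among the 10 splits of the libraries into 3 and 3 (one-sided exact permutation test, p = 0.1, the smallest the design allows), and the next highest split gave 0.0191. Within the 49 bp libraries the index was 51.03% for the same genotype (2 pairs) and 39.7% between genotypes (4 pairs). With full lists the difference was -0.0549 (exact p = 0.7).

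**Figure D3:**
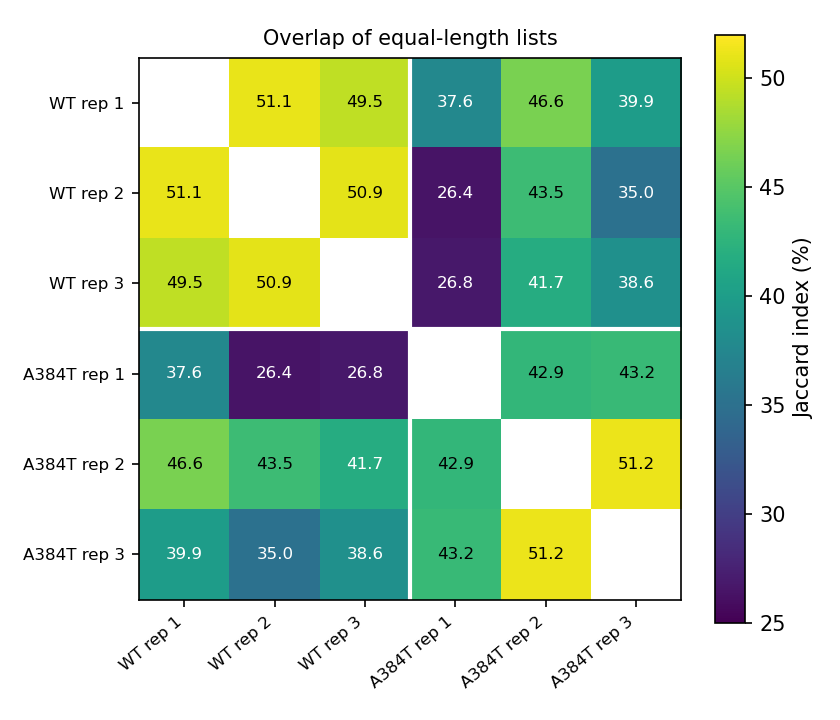
Jaccard index in percent between the 1746 strongest peaks of each pair of libraries; white lines separate the genotypes and the diagonal is left blank. Pairs of WT libraries reached 49.5 to 51.1%, and WT replicates 2 and 3 shared least with A384T replicate 1, at 26.4 and 26.8%.

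Few regions were restricted to one genotype in every replicate, and in the full lists more of them belonged to A384T. There were 46 regions with a peak in all 3 A384T libraries and in no WT library, which is 2.44% of the regions present in all 3 A384T libraries (exact 95% interval 1.79 to 3.24%). The reverse class held 3 regions, or 0.195% of the regions present in all 3 WT libraries (0.0402 to 0.569%). These counts rested on a few lists. With all lists reduced to 1746 peaks they were 133 for A384T and 120 for WT, and with lists matched in length between genotypes 39 and 9. Without WT replicate 1 the A384T count was 474 and without A384T replicate 3 it was 185; the WT count was 213 without WT replicate 2, 28 without A384T replicate 1, 15 without A384T replicate 2 and 6 without WT replicate 3. Leaving out a library lowers the requirement for presence or absence in its genotype to 2 of 2 libraries, so counts for the 2 genotypes are then not comparable.

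The 3 regions restricted to WT lay on chromosome 3 from 152604698 to 152605024 (fold 28.9 ± 17.3), chromosome 9 from 77278623 to 77279270 (14.0 ± 1.97) and chromosome 15 from 61271342 to 61271767 (12.7 ± 3.29; SD, n = 3 for each). Among the 46 regions restricted to A384T the best-ranked was chromosome 7 from 17397910 to 17398179, with a fold of 29.0 ± 2.89, followed among regions outside chromosome 5 by chromosome 7 from 95377000 to 95377452 (24.1 ± 5.30), chromosome 11 from 88919920 to 88920201 (23.0 ± 9.60) and chromosome 2 from 30319610 to 30319920 (16.8 ± 4.97; SD, n = 3 for each). The 46 regions had median rank percentiles of 76.5, 70.3 and 54.8 in A384T replicates 1, 2 and 3. Their median distance to the nearest peak of WT replicate 1 was 18.0 kb, with 4 of the 46 within 1 kb and 11 within 5 kb.

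Of the 10 best-ranked regions restricted to A384T, 6 lay in a row on chromosome 5 between 94419256 and 96085618, over 1666 kb, with gaps of 308 to 378 kb. Each of the 6 had a peak in every A384T library, with folds of 21.5 to 41.1 in replicate 1, 17.4 to 23.9 in replicate 2 and 7.89 to 13.2 in replicate 3. Over the row and 500 kb to either side the WT libraries had 0 peaks. A384T replicates 1, 2 and 3 had 10, 7 and 6 there, and these counts include the 6 peaks of the row itself.

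**Figure D4:**
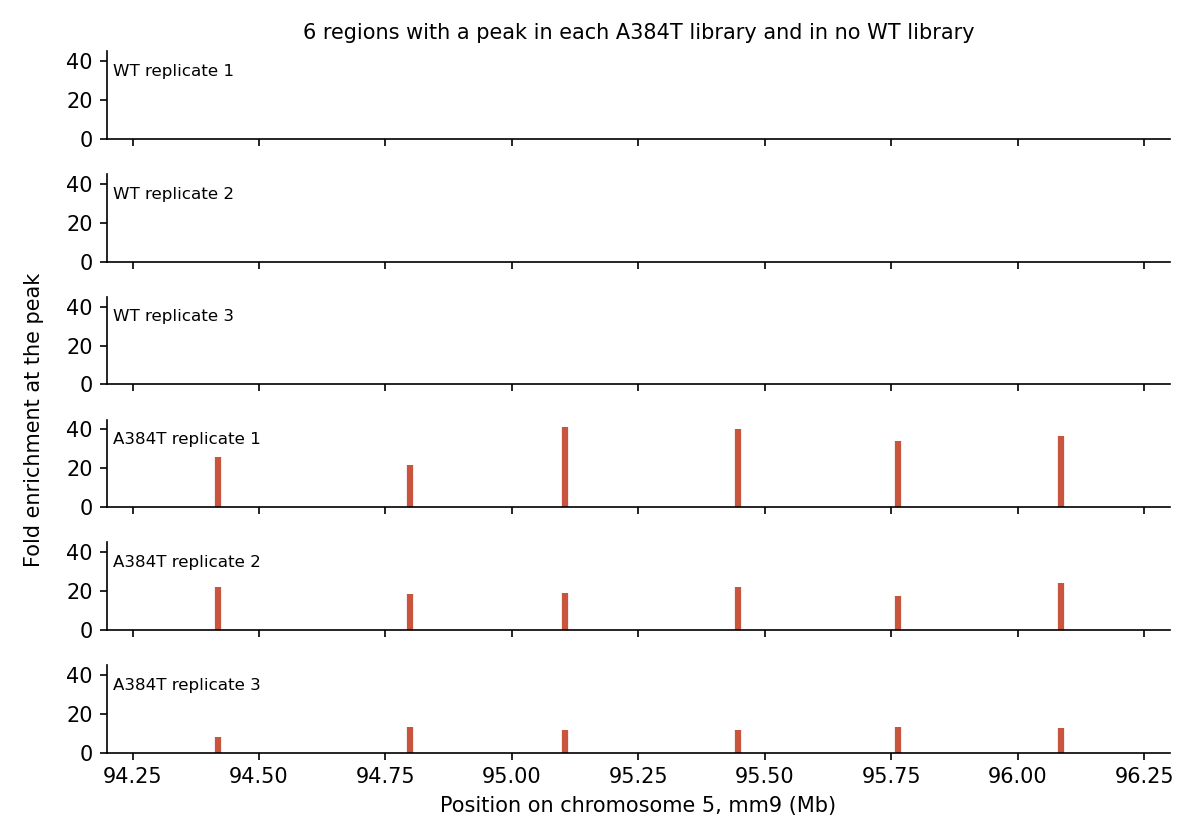
Peaks of the 6 regions on chromosome 5 in each library, with mm9 position in Mb on the horizontal axis and the authors' fold enrichment on the vertical axis; bar widths are not to scale. The A384T libraries have a peak at all 6 positions and the WT libraries at none.

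A wider class, with a peak in at least 2 libraries of one genotype and in none of the other, held 216 regions for WT and 189 for A384T. That is 5.78% of the 3739 regions found in at least 2 WT libraries and 3.10% of the 6088 found in at least 2 A384T libraries. The best-ranked WT region of this class was chromosome 6 from 129210094 to 129210416, with a fold of 33.2 ± 5.20 (SD, n = 2), and the best-ranked A384T region was chromosome 17 from 56464888 to 56465558, at 24.1 ± 7.47 (SD, n = 2). The WT regions lay close together: 50% of them shared a 1 Mb window with another, against a median of 20.8% in 10000 random draws of as many regions from the WT replicate 1 list (permutation p = 0.0001, the smallest the draws can give). Windows starting near 139 Mb on chromosome 1, 155 Mb on chromosome 2 and 123 Mb on chromosome 4 held 10 each. For A384T the share was 25.4% against 15.3% in draws from the A384T replicate 1 list (permutation p = 0.0051), and no window held more than 3. Of the 189 regions, 188 had a peak in A384T replicate 1 and 186 in A384T replicate 2. Draws from regions of both lists were not made for A384T. For WT, draws from regions of both replicates 1 and 3 raised the median to 28.6%, so clustering of the A384T regions is not established. With all lists reduced to 1746 peaks the counts were 340 for WT and 360 for A384T, and with lists matched in length 260 and 130. The WT count of 216 was 3 without WT replicate 1, 6 without WT replicate 3, 636 without A384T replicate 1 and 129 with only peaks of -log10 q of at least 20, a threshold at which the A384T count was 188. The A384T count of 189 was 3104 without WT replicate 1, 48 without A384T replicate 1 and 49 without A384T replicate 2. Leaving out a library turns at least 2 of 3 into 2 of 2 in its genotype, and absence then rests on 2 libraries. These counts therefore do not follow the same rule as 216 and 189.

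Within the 962 regions shared by all libraries the order of the peaks was on average less alike between genotypes than within them. The Spearman correlation by -log10 q averaged 0.640 over 6 pairs of the same genotype (0.594 to 0.693). Between genotypes it averaged 0.489 over 9 pairs (0.358 to 0.636). These ranges overlap, with 0.636 for WT replicate 1 and A384T replicate 1. Ranked by -log10 q inside the shared set, 239 regions (24.8%) had WT and A384T ranks that did not overlap. Of these, 128 ranked higher in every WT library and 111 higher in every A384T library. Chance gives 10%, or 96.2 regions, and the highest other split of the libraries gave 163. A region can count in only 1 of the 10 splits, so a high real count leaves less room in the others. The gap to 163 is therefore no separate measure. In the simulated lists 15.5% of unshifted regions were called once 100 others were shifted. The simulated noise and shifts were not set to the correlations seen here, so this share cannot be carried over. How much of the excess over 10% is shifted regions stays open. Chromosome 18 from 6764746 to 6765406 was at the 81.1 ± 2.07 percentile in WT and at 6.50 ± 4.55 in A384T, and chromosome 19 from 6363033 to 6363504 at 80.3 ± 4.32 and 8.84 ± 8.29. In the other direction, chromosome 7 from 80682526 to 80683296 was at 22.1 ± 17.4 in WT and 97.2 ± 0.318 in A384T, and chromosome 11 from 99099807 to 99100245 at 10.9 ± 4.00 and 80.4 ± 18.2 (SD, n = 3 throughout). Ranking by fold enrichment instead gave 153 regions (15.9%), against at most 129 in another split of the libraries, and 62 regions ranked higher in WT and 59 higher in A384T by both measures. These ranks describe order inside the shared set and not a level of binding, and 10 splits cannot give a share under 0.1.

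**Figure D5:**
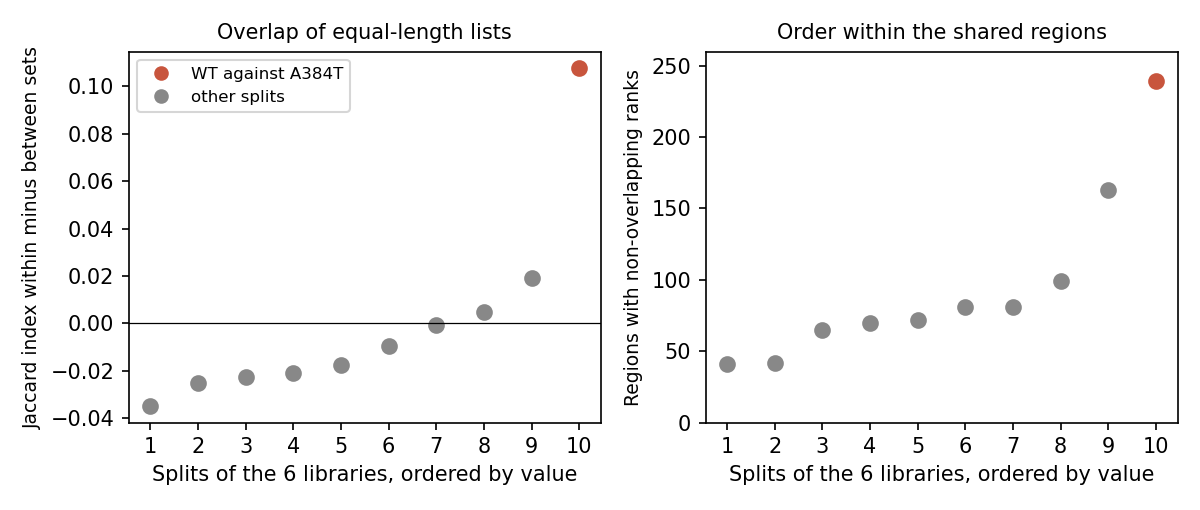
The 10 splits of the 6 libraries into 3 and 3, ordered by value, for the Jaccard index within minus between sets (left) and for the number of shared regions whose ranks by -log10 q do not overlap between sets (right). WT against A384T (red) gave 0.108 and 239, and the highest of the other splits (grey) gave 0.0191 and 163.

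The long replicate 1 lists, both reduced to 18147 peaks, held most peaks of the other libraries of either genotype. WT replicate 1 held 99.9% of the peaks of WT replicate 2 and 96.9% of WT replicate 3, where A384T replicate 1 held 97.2 and 88.3%. For A384T replicates 2 and 3 the WT reference held 94.8 and 96.5% and the A384T reference 93.7 and 99.2%. The WT reference exceeded the A384T reference by 5.66 points for WT libraries and by -0.778 points for A384T libraries, a difference of -6.44 that the test cannot resolve (two-sided exact permutation test, p = 0.333, the smallest 2 against 2 allows).

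Peak widths differed between genotypes by less than the spread between replicates. The median width in lists of 1746 peaks was 315 ± 161 bp in WT and 311 ± 126 bp in A384T (SD, n = 3 each), a difference of -4.17 bp (two-sided exact permutation test, p = 0.9) that became 86.5 bp without WT replicate 1 and 58.3 bp without A384T replicate 3. Among 21 chromosomes compared by their share of peaks, the genotypes did not overlap on chromosome 7 (WT 4.96 ± 0.264%, A384T 5.70 ± 0.380%) and chromosome 19 (WT 4.09 ± 0.381%, A384T 3.41 ± 0.308%; SD, n = 3 each). Both had a two-sided exact permutation p of 0.1, the smallest the design allows, and 0.933 after Benjamini-Hochberg adjustment, so no chromosome could pass in this design. Chromosome Y had 45, 56 and 95 peaks in WT replicates 1, 2 and 3 and 85, 94 and 0 in A384T replicates 1, 2 and 3. In WT replicate 2 all 56 lay between 2691983 and 2770450. Both replicate 1 lists also had 0 when reduced to their 2050 strongest peaks, while WT replicate 3 had 7 and A384T replicate 2 had 2 at that length.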

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

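All tests in this part that bear on chromosome Y were chosen after the result was seen.

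Peaks on unplaced sequences, which no comparison above uses, numbered 96, 7 and 25 in WT replicates 1, 2 and 3 and 100, 61 and 7 in A384T replicates 1, 2 and 3; every count exceeds the 3 that a count of 0 allows. Of these, 21, 3 and 9 in WT and 39, 37 and 0 in A384T lay on unplaced sequence of chromosome Y.

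A384T replicate 3 had no peak on chromosome Y, where the other libraries had 45 to 95. A short list may be the source: with each of the longer lists reduced to the 2050 peaks of this library, both replicate 1 libraries had 0. WT replicate 3 had 7 and A384T replicate 2 had 2 at that length, and WT replicate 2 had 56 with fewer peaks. Among the other 5 lists the counts of 0 thus came from the 51 bp libraries alone. An earlier test, which gave a chance of 0.0116 for no peak at the lowest share of the other lists, counted the peaks as independent although nearly all lie in 1 block, and was set aside for that reason. A control library from females cannot be judged as the source from the control background. At X peaks this background was 0.542 of that at autosomal peaks in this list (upper bootstrap limit 0.615, from 22 X peaks). The X value lies at the lowest background the peak caller allows, so the ratio is no measure of X dose. A control without chromosome Y would also have little background there, which would not by itself remove peaks. ChIP cells without a Y chromosome remain open: unplaced Y sequence had 0 peaks in this library and as few as 3 in another, too few to decide, and the sex of the animals is not in the labels.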

How the results depend on the processing

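Of 150 alternatives to 10 results, 119 left the value within the spread or within 1.5 times the count, 26 moved it and 5 reversed its sign; the thresholds of -log10 q of 20, matched lengths, 1 Mb windows, removal of chromosome Y, ranks by fold, and all alternatives for the 3 of 3 counts and the rank comparison were chosen after the data were seen. The planned -log10 q of at least 10 removes no peak, since it equals the authors' cutoff. The replicate block changes only the test and not the value. Both alternatives count among the 119 by construction. Motif, promoter and gene list results were not analysed here.

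The Jaccard difference of 0.108 became -0.0549 with full lists, where overlap follows list length by construction. With lists of 1746 peaks the regions restricted to one genotype numbered 340 for WT and 360 for A384T in at least 2 libraries, 120 and 133 in 3 of 3, and 500 regions were in all 6. Requiring 3 of 3 gave 3 and 46. Summits within 200 bp gave 241 WT and 300 A384T regions in at least 2 and 8 WT regions in 3 of 3. In at least 2, WT and A384T regions numbered 129 and 188 at -log10 q of 20 and 139 and 163 as 1 Mb windows, and WT regions in 3 of 3 numbered 9 with matched lengths. Ranks by fold gave 15.9%.

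Leaving out 1 library gave 3 to 636 WT and 48 to 3104 A384T regions in at least 2, 3 to 213 WT and 46 to 474 A384T regions in all remaining libraries of one genotype and none of the other (2 of 2 where its own library was left out), and 963 to 1494 regions in all libraries. The log2 difference in peaks ran from -0.52 to 1.27, reversing to -0.52 without WT replicate 2 and -0.50 without A384T replicate 1, and the width difference from -67.9 to 86.5 bp, reversing to 86.5 without WT replicate 1 and 58.3 without A384T replicate 3. The Jaccard difference ran from 0.0702 to 0.146, recovery from -9.41 to -3.47 points, and the share of regions with non-overlapping ranks from 30.1 to 36.0%, where chance gives 20%. Apart from full lists, where construction gives the cause, the cause was not tested. Absence rests mostly on the long replicate 1 lists.

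Replicate numbers were not taken to pair the libraries, a choice made after the values with replicate blocks had been computed. Same-numbered libraries correlated in their deviations from the group means at -0.188, -0.235 and -0.150 by presence, at 0.435, 0.123 and 0.374 by rank of -log10 q and at 0.141, 0.0023 and 0.208 by rank of fold, so 1 of 3 measures passed 0.1 throughout. By -log10 q each library correlated best with its own number. The replicate block changes the test and not the values, which were 0.27 for peaks, -4.17 for width, 0.108 for overlap and -6.44 for recovery. The exact permutation p was then 1, 1, 0.25 and 0.5, where 0.25 is the smallest 3 pairs allow, and no call changed. In 438 shared regions (45.5%, chance 25%) all 3 same-numbered pairs differed in the same direction by rank of -log10 q. Exchanging genotypes in 1 or 2 pairs gave 16.2 to 21.0%. Among the 4 splits that part every number, regions with non-overlapping ranks numbered 239 for the real split and at most 65 in the others. By fold these numbers were 153 and 81. A region can count in only 1 split or exchange, so the real rank counts limit the others. Restricted regions numbered 405 and 488 in at least 2, and 49 and 74 in 3 of 3. These 4 splits cannot give a share under 0.25.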

Other observations

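Apart from the splits for regions in at least 2 libraries, the tests in this part were chosen after the data were seen.

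Several 1 Mb windows were dense in peaks in most libraries. The window starting at 32 Mb on chromosome 9 held 105, 29 and 41 peaks in WT replicates 1, 2 and 3 and 65, 48 and 18 in A384T replicates 1, 2 and 3, and that at 11 Mb on chromosome 19 held 95, 36 and 43 and 53, 49 and 19. The window at 123 Mb on chromosome 4 was uneven, with 150, 0 and 41 peaks in WT and 56, 6 and 4 in A384T. On chromosome Y the peaks of WT replicate 1 were up to 7418 bp wide and covered 90.2% of a block of 82.4 kb, against 14.7% of 78.5 kb in WT replicate 2.

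More regions were restricted to A384T than to WT in 3 of 3 libraries (46 against 3). A single block at 1 position counted many times is argued against by 42 windows of 1 Mb against 3. The longest run among the 46 held 6 regions, on chromosome 5. Windows by position cannot detect repeats dispersed over the chromosomes, which were not tested. Calls near the peak threshold remain open, with a median rank percentile of 54.8 in the A384T replicate 3 list, the shortest of the 3 (bootstrap interval 37.8 to 61.2). In A384T replicates 1 and 2 the medians were 76.5 and 70.3. At -log10 q of at least 20 the 3 of 3 counts were 37 for A384T and 2 for WT. That cutoff also changes which regions count as absent, so it does not settle the question. Longer A384T lists cannot be told apart from a genotype effect: with lists matched in length the counts were 39 and 9, a ratio of 4.33 whose interval reaches down to 2.07, with all lists at 1746 peaks they were 133 and 120, and in at least 2 libraries at matched lengths WT had more, 260 against 130, whereas at -log10 q of at least 20 A384T had more, 188 against 129. Copy number and strain sequence of the ChIP cells at the row on chromosome 5 were not tested, and the control background there was 0.703, 0.788 and 1.03 of the list median in A384T replicates 1, 2 and 3.

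The 216 regions found in at least 2 WT and no A384T libraries lay close together. Dense windows of the WT lists are argued against as the whole cause, since 0 of 10000 random draws from WT replicate 1 were as clustered (permutation p = 0.0001, the smallest possible). Of the 216, 213 were in both WT replicates 1 and 3, and 50.7% of these shared a window; draws from the 3614 regions of both lists, matched on rank in WT replicate 3, had a median of 31.5% and reached it in 0 of 10000 (permutation p = 0.0001). The count was 3 without WT replicate 1 and 6 without WT replicate 3, but membership then needs a peak in WT replicate 2. Of the 1664 regions of that short list 98.7% had a peak in A384T replicate 1, so low counts were bound to follow. Whether the pattern belongs to that pair of libraries or to the genotype therefore cannot be told.

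For the counts of regions and the rank order the 10 splits of 6 libraries cannot give a share under 0.05. Regions in at least 2 of 3 against none totalled 405 for the real split and up to 9992 in another. Counting the real split itself, 6 of the 10 splits were at least as high. In 3 of 3 they totalled 49 and up to 2399, with 5 of 10 at least as high, again counting the real split. The highest counts in both classes came from splits with both replicate 1 libraries on one side. Their lists shared 13567 regions, while the next longest list held 6346. In at least 2 libraries such splits were thus bound to give high counts by list length alone, and cannot serve as a reference for the real split. The replicate 1 libraries differ from the rest in list length, tag length and redundancy together. In the 3 of 3 class the split of WT replicates 1 and 3 with A384T replicate 2 also exceeded the real one, with 74. Shared regions with non-overlapping ranks numbered 239 in the real split and up to 163 in another, so 1 of 10 was as high, and the second highest also put both replicate 1 libraries together. By fold the numbers were 153 and up to 129. By either measure a region can count in only 1 of the 10 splits, so the real count limits the others.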
